A study of Mus musculus with 20 samples.

How the data were processed

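Gene expression was measured with 1-colour microarrays in the livers of 20 mice that carried estrogen receptor alpha (wild type) or lacked it (null), ovariectomized at 4 weeks of age and gavaged at 9 weeks with placebo or with estradiol (E2). The 4 groups of genotype and treatment came from the genotype and treatment that the labels give each animal, with 5 animals per group and 1 array per animal. Animals were separate, so the p-value of a single gene measures the spread between animals. Which animals shared a cage of 5 is not given in the sources used here.

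Per the labels' protocols, liver pieces were snap-frozen 4 hours after gavage, and total RNA with an integrity number above 9 was amplified and labelled with Cy3. Per the file headers, images were extracted with Agilent Feature Extraction 10.10.1.1, which gave for each spot a mean, a median and a local background intensity and a processed intensity that was background-subtracted and detrended within the array. The headers place the probes on the mouse build mm9, and coordinates are given on that build. The authors also deposited a table of log2 values for 32526 probes on the 20 arrays, and the submitters' processing notes name limma with no version. Set against the scanner values, each column of that table followed the log2 median signal of its array (correlation across probes from 0.9987 to 1.0), and each column had a median of 7.85, as quantile normalization without background subtraction gives. Scale and direction of that table were settled by this comparison, and no centring of genes was seen. How those probes were chosen is not given in the sources used here. The table was used as an alternative.

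The processed intensity was taken as log2 minus the 75th percentile of each array over its 59305 non-control spots. Spots that the files mark as non-uniform (0 to 16 per array) were left out, no spot was saturated, and spots of the same probe were averaged. A probe was kept where the files call it well above background on at least 4 of 5 arrays of at least 1 group, which left 30961 of 55681 probes. For the 6128 genes with several kept probes the brightest was used, which left 21998 genes, each with a log2 level per array. Array names were old, so 27235 probes were named through their accession in a table of RefSeq genes, 3581 through a current symbol and 565 through a synonym, and 24300 kept the name in the array file. No coordinate was taken from the RefSeq table.

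Differences were tested with limma 3.58.1 in R 4.3.3 with data.table, version 1.17.8, in 1 fit of the 4 group means over all 20 arrays with 16 residual degrees of freedom (2.44 prior degrees of freedom), 2-sided, with Benjamini-Hochberg adjustment over all genes within each of 5 contrasts and a threshold of 0.05. The contrasts were E2 against placebo in wild types, E2 against placebo in nulls, the difference between these effects, and null against wild type under placebo and under E2. An error given as SE is that of the fit, and one given as SD is that of 5 animals. Where no array of a group was well above background for a gene, a fold is given as at least the brighter group's mean over the dimmer group's mean, with the dimmer group's arrays set no lower than the dimmest probe well above background on that array. Several such genes also have a fitted log2 change, which is not a bound. Where only some arrays of the dimmer group were well above background, the fitted log2 change of a called gene is given without a fold.

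Gene lists (35, of liver pathways, hormone responses and markers of other cell types a piece of liver can hold) were written from textbook knowledge before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members (34) were tested against all other genes with limma's camera, with a preset correlation of 0.01, over the 21972 genes with all 20 values, and adjusted over the lists of a contrast. At that preset correlation camera takes genes largely as its units, so its p-values are not a measure of the spread between animals. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside this test. Members past the threshold were also counted when adjusted over the list alone.

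The genes named were those with an adjusted p under 0.05, no overlap between the 2 groups compared (not asked of the difference between genotypes) and a gene symbol, namely the 10 largest increases and 10 largest decreases for E2 in wild types and for null against wild type under placebo, and 5 and 5 in the other contrasts. Up to 4 members with the smallest adjusted p of each list that passed its camera test, and Esr1, Esr2 and Gper1, were named as well. A gene named outside this rule is marked as such.

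The fit and the list test were also tested on simulated data, drawn from normal distributions with the fitted means and variances and with no correlation between genes. In 20 simulated sets of the E2 comparison in wild types over 21998 genes, 36.6% of genes changed by 0.5 on the log2 scale were recovered, 79.5% of those changed by 1, 96.3% by 2 and 98.8% by 3, and 5.3% of the calls were false. The simulated comparison without changes, that of E2 in nulls, gave a median of 1 call and at most 2.

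The precision is limited by the number of arrays. Between 51.6% and 70.0% of non-control spots were well above background on an array, and the 75th percentile of the processed intensity lay between 294 and 466. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' deposited values, no filter and a stricter filter, the mean of a gene's probes, non-uniform spots kept, slide as a fixed or random block and within slides, the replicate number as a block, only the arrays compared, array weights, a trended robust fit, and each array left out in turn. A block for animals numbered below 750 in the labels, a fit without them, each array left out for the list tests, and the mean of both null contrasts were added after seeing the data. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.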

Results

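Transcript levels were measured in the livers of ovariectomized mice 4 hours after a single gavage with estradiol (E2, the main circulating estrogen, at 1 mg/kg) or placebo (castor oil with 5% ethanol). Mice either carried estrogen receptor alpha (wild type) or lacked it (null), and the labels state that both genotypes descended from the same parents. Each of the 4 groups held 5 animals of 9 weeks, with 1 array each. The design asks which liver transcripts respond to E2 and which of these responses need the receptor. The 20 arrays lay on 4 slides, each scanned once on the same day, and no slide held 1 group alone. Arrays of the same group correlated across genes at 0.981 to 0.995 and arrays of different groups at 0.978 to 0.993. The share of spots well above background ran from 51.6% in null placebo animal 1 to 70.0% in wild-type E2 animal 1. Levels are log2 intensities relative to the array's 75th percentile, and each coordinate is that of the probe on mm9.

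Esr1, which encodes estrogen receptor alpha, was lower in every null liver than in every wild-type liver. Under placebo its level was 0.39 ± 0.25 in wild types and -1.61 ± 0.48 in nulls (SD, n = 5 each), a 4.00-fold decrease (log2 -2.00 ± 0.23, SE) with an adjusted p of 0.000487. Under E2 it was 4.70-fold lower in nulls (log2 -2.23 ± 0.23), with an adjusted p of 1.82e-05. The probe lay on chromosome 10 from 5343056 to 5343115. The other kept Esr1 probes, starting at 5379218 and 5489352, were at least 2.89-fold and 3.19-fold lower in nulls under placebo (adjusted p over all probes of 5.03e-05 and 0.0051), the first being well above background on 0 null placebo arrays and 2 null E2 arrays. Under E2 they differed by -1.45 and -1.59 on the log2 scale. All null arrays still read well above background at the brightest probe, and the labels do not say which part of the gene was deleted, so a remaining transcript cannot be placed inside or outside it. Esr2, which encodes estrogen receptor beta, differed by -0.13 between nulls and wild types under placebo (adjusted p = 0.767), and Gper1, a membrane estrogen receptor gene, by -0.36 (adjusted p = 0.604).

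The first comparison asked which transcripts E2 changed in wild-type livers. Slc34a2, a sodium-dependent phosphate transporter, went from not well above background on any placebo array to well above it on all 5 E2 arrays, a rise of at least 24.2-fold (log2 5.90 ± 0.39, SE, n = 5 per group). Corin, the protease that activates the precursor of atrial natriuretic peptide, rose at least 8.43-fold (log2 3.71 ± 0.40), and Gdf15, a secreted stress-induced cytokine, rose 10.3-fold (3.36 ± 0.39). Mmd2, a membrane protein gene of the progestin and adipoQ receptor family, rose 10.4-fold (3.38 ± 0.32), and Hrob, a homologous recombination factor, 9.31-fold (3.22 ± 0.34). The epithelial keratin genes Krt4 and Krt79 rose at least 2.94-fold (3.10 ± 0.39) and 5.53-fold (2.47 ± 0.21). Rab44, a large Rab GTPase, rose by a log2 of 2.95 ± 0.29, Trex2, a DNA exonuclease, by 2.83 ± 0.45, and Asb2, a substrate-binding subunit of a ubiquitin ligase, rose 5.23-fold (2.39 ± 0.29). At these probes 0 placebo arrays were well above background for Krt4, 1 of 5 for Trex2 and 3 of 5 for Rab44. Under normexp background correction the log2 rises were smaller, at 2.59 for Slc34a2, 1.33 for Corin, 1.91 for Hrob, 0.58 for Krt4, 1.23 for Rab44, 0.85 for Trex2 and 1.42 for Asb2, so their size depended on that choice. Decreases were fewer and smaller. Aspm, a mitotic spindle protein gene above background on 2 of 5 E2 arrays, fell (log2 -1.47 ± 0.30), Cebpa, a transcription factor of differentiated hepatocytes, fell 1.54-fold (-0.62 ± 0.12), and Rai14, an actin-associated protein gene, fell 1.5-fold (-0.58 ± 0.09). Esr1 itself differed by 0.21 ± 0.23 with E2 (adjusted p = 0.83).

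With limma, 70 of 21998 genes passed an adjusted p of 0.05 in wild types, 66 higher and 4 lower with E2, and 47 of them changed at least 2-fold. In 67 of the 70 genes every E2 animal lay on 1 side of every placebo animal. Adjusted p-values were 8.96e-08 for Slc34a2, 2.72e-05 for Corin, 9.78e-06 for Mmd2, 7.39e-05 for Gdf15, 2.72e-05 for Hrob, 0.000164 for Krt4, 1.4e-05 for Rab44, 0.00324 for Trex2, 2.37e-06 for Krt79 and 0.000135 for Asb2. For the decreases they were 0.0355 for Aspm, 0.0202 for Cebpa and 0.00221 for Rai14. The probes lay on chromosome 5 at 53462121 to 53462180 for Slc34a2, 72692288 to 72692347 for Corin and 143039928 to 143039987 for Mmd2, on chromosome 8 at 73153293 to 73153352 for Gdf15, and on chromosome 11 at 102126433 to 102126492 for Hrob. Those of Krt4 and Krt79 lay close together on chromosome 15, at 101750158 to 101750736 and 101759764 to 101759823. The Rab44 probe lay on chromosome 17 at 29285831 to 29285890, the Trex2 probe on chromosome X at 70679045 to 70679104, and the Asb2 probe on chromosome 12 at 104559752 to 104559811. The Cebpa probe lay on chromosome 7 at 35906517 to 35906576 and the Rai14 probe on chromosome 15 at 10498852 to 10498911. With only animals numbered 750 or above 41 genes were called, 39 of them among the 70. Scaling on the array median gave 32 genes, 31 of them among the 70, and ended the call of Rai14, and a fit of wild-type arrays alone gave 46, with 42 among the 70. The call of Aspm ended without wild-type placebo 2, 3 or 4, wild-type E2 1 or 3 or null E2 3 and in 9 other settings (-1.77 to -0.32 over all). That of Cebpa ended without wild-type placebo 3, 4 or 5 or wild-type E2 1 or 2 and in 6 others (-0.85 to -0.46). Within the slides that held both groups the named calls kept their sign in 39 of 39 values. Genes named for groups that do not overlap must do so, so this is no test of slides. With slide as a block 50 genes were called and the calls of Aspm and Cebpa ended.

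**Figure D1:**
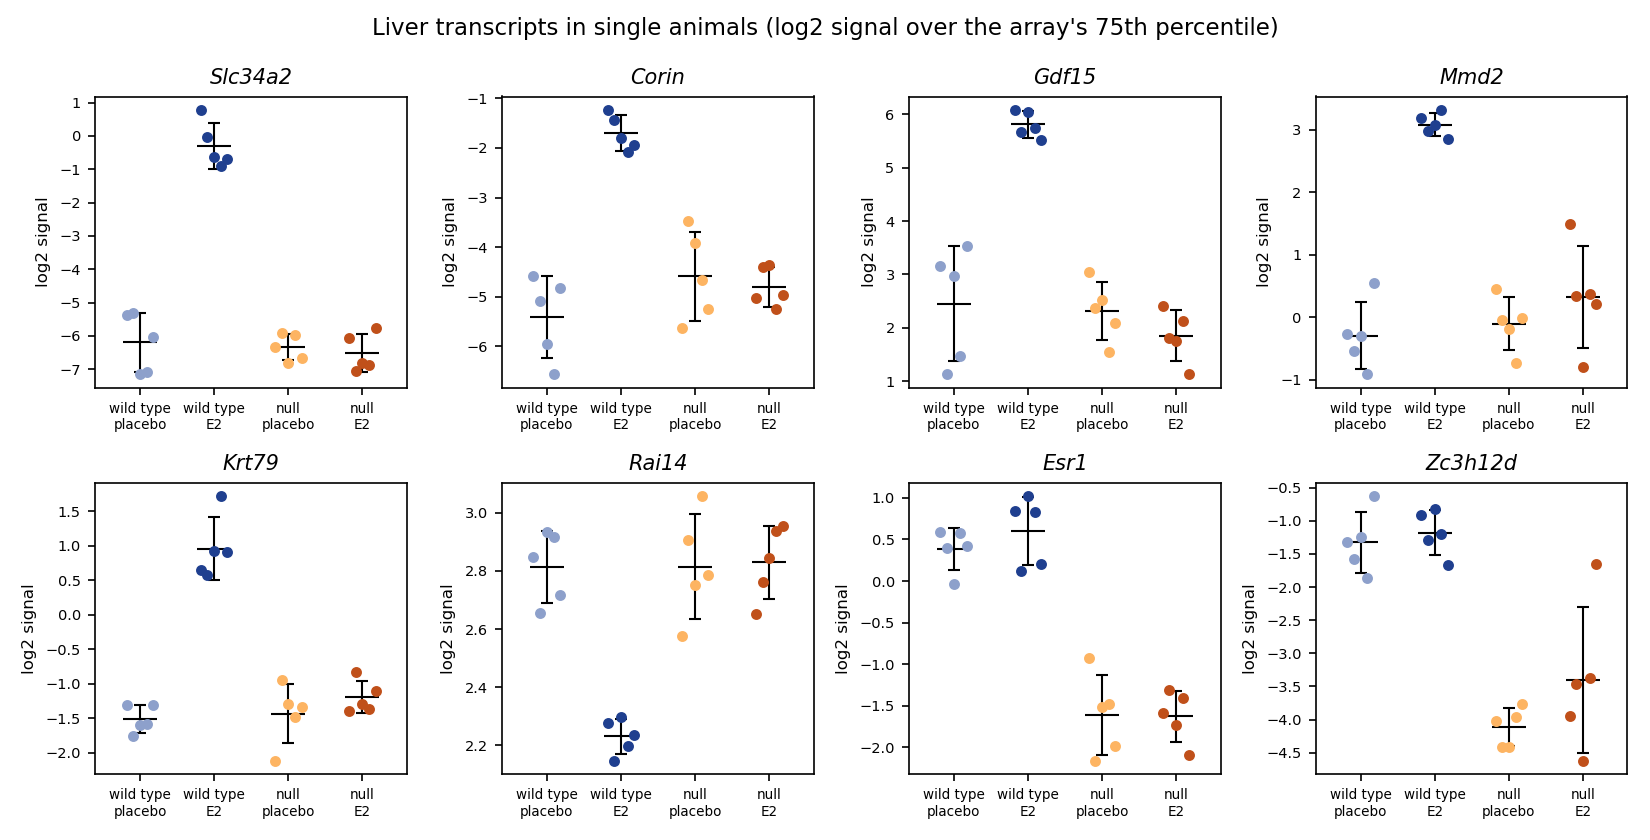
Level of 8 genes on each of the 20 arrays by group, as log2 intensity relative to the array's 75th percentile, with 1 dot per animal and the mean ± SD of 5 animals. Gdf15 stood at 2.45 ± 1.08 and 5.81 ± 0.25 in wild types under placebo and E2, and at 2.31 ± 0.55 and 1.85 ± 0.48 in nulls.

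Among the gene lists, camera called 9 for E2 in wild types. None of the 9 kept an adjusted p under 0.05 with an estimated correlation, so they are given as shifts of members. All 8 erythroid genes, globins and other red cell genes, lay above 0 with E2 (median 0.51, camera adjusted p = 1.85e-07, adjusted p = 0.167 with an estimated correlation), with 0 called over all genes and 7 adjusted over the list alone. Hba-a1, an alpha globin gene, was 1.41-fold higher (adjusted p = 0.33). All 15 Kupffer cell markers, of the resident macrophages, lay above 0 (median 0.26, camera adjusted p = 0.00683, adjusted p = 0.788 with an estimated correlation). So did 11 of 12 T and NK cell markers (median 0.22, camera adjusted p = 0.0334, adjusted p = 0.674 with an estimated correlation), and 0 members of either were called when adjusted over the list alone. All 5 adipose markers lay above 0 (median 0.40, camera adjusted p = 0.0279, adjusted p = 0.167 with an estimated correlation), with 0 adjusted over the list alone. The list of hepatocyte transcription factors had 17 of 20 members below 0 (median -0.14, camera adjusted p = 0.00102, adjusted p = 0.167 with an estimated correlation). Cebpa was its member called over all genes and adjusted over the list alone, and Onecut1 and Foxa3 were 2.21-fold and 1.38-fold lower without passing (adjusted p of 0.507 and 0.467). Glucocorticoid targets had 16 of 20 members above 0 (median 0.21, camera adjusted p = 0.00554, adjusted p = 0.699 with an estimated correlation) with 2 adjusted over the list alone, among them Sds, a serine dehydratase gene, 1.62-fold higher with an adjusted p of 0.302 over all genes. Immediate early genes had 18 of 25 members above 0 (median 0.29, camera adjusted p = 0.00897, adjusted p = 0.674 with an estimated correlation). Endoplasmic reticulum stress genes had 18 of 23 below 0 (median -0.16, camera adjusted p = 0.0313, adjusted p = 0.788 with an estimated correlation). Cell cycle genes had 20 of 24 below 0 (median -0.14, camera adjusted p = 0.0334, adjusted p = 0.769 with an estimated correlation). Each of these had 0 members adjusted over the list alone. Of 29 known estrogen targets 19 lay above 0 (median 0.04, camera adjusted p = 0.58). Fry called the erythroid and hepatocyte transcription factor lists (adjusted p = 0.0494 each). The camera calls of those lists held without any single array, and those of the other 7 ended without 1 or more of wild-type E2 animals 1, 2, 3 and 5 and wild-type placebo animals 1 to 5, while 14 lists were called without wild-type placebo 4. With only animals numbered 750 or above 5 of the 9 were called. Quantile scaling ended the calls of endoplasmic reticulum stress genes and T and NK cell markers, median scaling those of endoplasmic reticulum stress and cell cycle genes, and the deposited values that of T and NK cell markers. Slide as a block ended the calls of cell cycle and immediate early genes, slide as a random block that of T and NK cell markers, and a block for the animals numbered below 750 that of cell cycle genes. Within slides 20 of 27 medians of the called lists kept their sign. Those of glucocorticoid targets (-0.183 and -0.328) and immediate early genes (-0.051 and -0.202) turned in slides 1 and 4, so that these shifts held in 1 of 3 slides.

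In null livers E2 left the genes it moved in wild types near their placebo levels. Across the 66 genes that rose in wild types, the mean rise there was 1.60, and in nulls the mean differed by -0.009 ± 0.042 (SE, n = 5 per group), with an exact 2-sided permutation p of 0.849 over 252 splits, whose smallest possible p is 0.00794. Slc34a2 differed by -0.17 ± 0.39 in nulls, Corin by -0.21 ± 0.40, Gdf15 by -0.47 ± 0.39 and Mmd2 by 0.43 ± 0.32, with adjusted p-values from 0.893 to 0.979. With limma, 0 of the 66 genes were called in nulls and 5 had an unadjusted p under 0.05. Catsper2, a subunit of the sperm calcium channel, was the gene called for E2 in nulls, at 1.58-fold higher (log2 0.66 ± 0.09, adjusted p = 0.0157, chromosome 2, 121218394 to 121218453), against 1331 genes with an unadjusted p under 0.05. A second Catsper2 probe differed by 0.24 (adjusted p = 0.817 over all probes). The call ended without null E2 animals 1, 2 or 4 or null placebo animals 2 or 4, and in 6 other settings, which gave 0 genes by limma and 829 to 1464 at an unadjusted p under 0.05. Slide as a block gave 2 genes. Catsper2 kept its sign in 3 of 3 slides, as a gene whose groups do not overlap must.

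The difference between the E2 effects was then tested itself. E2 raised Slc34a2 by 6.07 ± 0.55 more on the log2 scale in wild types than in nulls (SE, n = 5 per group, adjusted p = 1.8e-05) and Corin by 3.93 ± 0.56 (adjusted p = 0.00242). The difference was 3.83 ± 0.56 for Gdf15 (adjusted p = 0.00257), 2.95 ± 0.45 for Mmd2 (adjusted p = 0.00443) and 2.87 ± 0.55 for Krt4 (adjusted p = 0.0338). Slc34a2, Corin and Krt4 were at or near background in the other groups, and under normexp background correction their differences were smaller, at 2.60, 1.35 and 0.64. Krt79 (2.23, adjusted p = 0.00128), Rab44 (2.63, 0.00496), Hrob (2.75, 0.0167) and Asb2 (2.28, 0.0195) passed as well. Catsper2 went the other way (-0.81 ± 0.13, adjusted p = 0.00496), but its second probe did not pass (-0.27, adjusted p = 0.757 over all probes), and its call ended with the mean of its probes, with median scaling and with only animals numbered 750 or above. Trex2 (2.71, adjusted p = 0.166), Cebpa (-0.61, 0.353), Aspm (-1.24, 0.57) and Rai14 (-0.60, 0.0804) did not pass. In all, 36 genes passed, 34 with a more positive effect in wild types and 2 with a more negative one. Of the 66 genes that rose in wild types 34 passed, and 65 did when adjusted over the list alone, a list chosen on these arrays and so not independent evidence. Of the 4 that fell, 0 passed over all genes with limma and 4 adjusted over the list alone, and 1625 genes had an unadjusted p under 0.05. The call of Krt4 ended when any 1 of 13 arrays was left out and in 5 other settings. Median scaling gave 18 genes, 17 of them among the 36. A fit without the animals numbered below 750 gave 10, all among the 36, and ended the calls of Corin, Gdf15, Mmd2, Krt4 and Catsper2 (largest adjusted p over the alternatives of 0.207, 0.379, 0.171, 0.857 and 0.605). Within slides 1 and 2, which alone held all 4 groups, Slc34a2, Corin, Gdf15, Mmd2, Krt4 and Catsper2 kept their sign in 12 of 12 values.

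**Figure D2:**
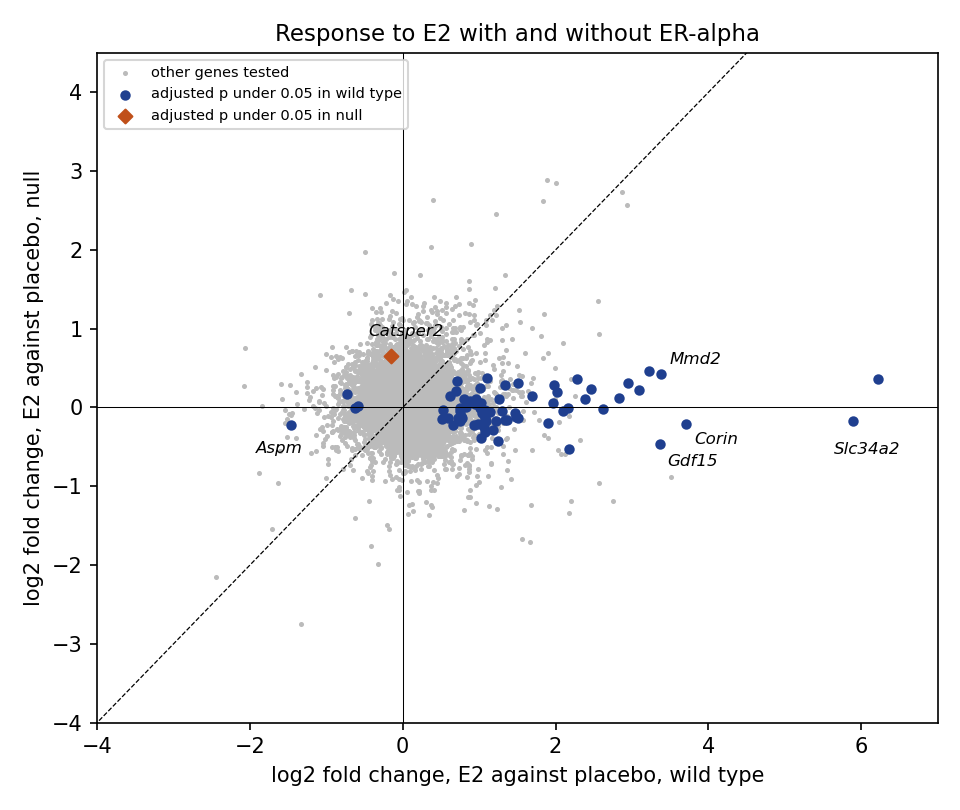
Log2 fold change with E2 in null livers against that in wild-type livers for the genes tested, 1 dot per gene, with the 70 genes called in wild types and Catsper2 marked. Slc34a2 lies at 5.90 in wild types and -0.17 in nulls.

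Camera called 12 lists for E2 in nulls, and each had an adjusted p of 0.71 with an estimated correlation and 0 members called, over all genes or adjusted over the list alone. Of the male-biased liver genes, those with higher levels in male livers, 21 of 23 lay below 0 (median -0.36, camera adjusted p = 4.8e-06, adjusted p = 0.71 with an estimated correlation), such as Cyp4a12a, a fatty acid hydroxylase gene (log2 -1.76 ± 0.70, adjusted p = 0.818). Of the female-biased genes 22 of 30 lay above 0 (median 0.12, camera adjusted p = 0.0245), and Sult2a1, a sulfotransferase gene, differed by 2.88 ± 1.71 (adjusted p = 0.84). Glucocorticoid targets had 19 of 20 members below 0 (median -0.30, camera adjusted p = 0.000553), and glucose metabolism 22 of 26 (median -0.13, 0.00222). Fatty acid synthesis had 25 of 27 below 0 (median -0.12, 0.00395), periportal genes 16 of 19 (median -0.12, 0.019) and coagulation 23 of 26 (median -0.07, 0.0245). Endoplasmic reticulum stress genes had 19 of 23 below 0 (median -0.12, 0.0245), acute phase 26 of 31 (median -0.09, 0.0327) and stellate cell markers 14 of 16 (median -0.09, 0.0396). Fatty acid oxidation genes had 22 of 32 members above 0 (median 0.08, camera adjusted p = 0.0419) and Kupffer cell markers 14 of 15 (median 0.18, camera adjusted p = 0.0396). For each of these the adjusted p = 0.71 with an estimated correlation. The camera calls of male-biased, glucocorticoid and glucose genes held without any single array, and those of the others ended without 1 or more of null E2 animals 1, 3, 4 and 5 and null placebo animals 1, 3 and 5. There were 7, 6 and 7 lists called without null placebo 1, 3 and 5. Quantile scaling and the deposited values each ended the calls of acute phase, coagulation and periportal genes, the deposited values that of stellate markers, and median scaling that of fatty acid oxidation. The replicate block ended those of fatty acid oxidation, Kupffer and stellate genes. Slide as a block ended the calls of endoplasmic reticulum stress, fatty acid oxidation, female-biased, Kupffer and stellate genes, and a block for the animals numbered below 750 those of acute phase, endoplasmic reticulum stress, fatty acid oxidation and Kupffer genes. With only animals numbered 750 or above 0 of the 12 were called, so the calls of male-biased, glucocorticoid and glucose genes ended there too, at medians of -0.064, -0.106 and -0.003. Within slides 27 of 36 medians kept their sign, and those of endoplasmic reticulum stress (0.072 and 0.021, slides 1 and 3) and fatty acid oxidation (-0.003 and -0.009, slides 1 and 2) turned in 2 of 3 slides.

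For the difference between genotypes camera called 8 lists, and 0 passed with an estimated correlation (smallest adjusted p = 0.316). For glucocorticoid targets the difference lay above 0, a more positive E2 effect in wild types, in 19 of 20 members (median 0.44, camera adjusted p = 2.96e-06, adjusted p = 0.462 with an estimated correlation), with 2 members passing when adjusted over the list alone. The same held for 8 of 8 erythroid genes (median 0.58, camera adjusted p = 1.44e-06, adjusted p = 0.332 with an estimated correlation, 6 adjusted over the list alone). It held for 5 of 5 adipose markers (median 0.58, camera adjusted p = 0.015, adjusted p = 0.316 with an estimated correlation, 0 over the list). It also held for 20 of 25 immediate early genes (median 0.29, camera adjusted p = 0.00194, adjusted p = 0.487 with an estimated correlation, 0 over the list). Periportal genes (16 of 19 members, median 0.17, camera adjusted p = 0.00705, adjusted p = 0.473 with an estimated correlation, 2 over the list) shifted the same way. Glucose metabolism did so in 20 of 26 members (median 0.19, camera adjusted p = 0.0158, adjusted p = 0.662 with an estimated correlation, 1 over the list). Hepatocyte transcription factors (17 of 20 below 0, median -0.15, camera adjusted p = 0.0115, adjusted p = 0.332 with an estimated correlation, 1 over the list) shifted down. Cell cycle genes did so in 19 of 24 members (median -0.17, camera adjusted p = 0.0166, adjusted p = 0.662 with an estimated correlation, 0 over the list). Within slides 1 and 2, which alone held all 4 groups, 16 of 16 medians of the called lists kept their sign. In slide 1 those of cell cycle genes (-0.007) and glucocorticoid targets (0.046) lay near 0. Sds differed by 1.12 ± 0.28 (adjusted p = 0.233) and Jun, an immediate early gene, by 0.97 ± 0.32 (adjusted p = 0.55). The calls of adipose markers ended without wild-type E2 animal 1, of glucose metabolism without wild-type E2 animal 2 or wild-type placebo animals 4 or 5, and of cell cycle genes without any of 5 arrays (null E2 4, null placebo 1 and 3, wild-type E2 1 and wild-type placebo 4). Slide as a block ended the calls of glucose metabolism and cell cycle genes, and a block for the animals numbered below 750 those of hepatocyte transcription factors and cell cycle genes. With only animals numbered 750 or above 2 of the 8 were called.

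The next comparison asked what the loss of the receptor changed without E2. Rgs3, a regulator of G-protein signalling, was 9.34-fold lower in nulls under placebo (log2 -3.22 ± 0.43, SE, n = 5 per group) and Esr1 4.00-fold lower. Zc3h12d, an RNase gene of the Regnase family, was lower by a log2 of -2.79 ± 0.38 and A330032P22Rik by -1.67 ± 0.26, with 3 and 2 of 5 null arrays above background. Foxq1, a forkhead transcription factor gene, was 3.15-fold lower (-1.66 ± 0.30) and Rad51b, a DNA repair gene, 3.02-fold lower (-1.60 ± 0.28). Under normexp background correction the changes were smaller for Zc3h12d (-1.31), A330032P22Rik (-0.51), Efr3b (-0.45), BC037704 (-0.38), Snhg11 (0.83) and Slc26a4 (0.48). Gm6524 (2.18-fold, -1.12 ± 0.11), Efr3b, a plasma membrane protein gene (2.05-fold, -1.03 ± 0.14), and BC037704 (1.72-fold, -0.78 ± 0.13) were lower too. Higher in nulls were Snhg11, a noncoding host gene of small nucleolar RNAs, 2.73-fold (1.45 ± 0.26), Slc26a4, the anion exchanger pendrin, 2.09-fold (1.06 ± 0.19), and Alas2, the erythroid enzyme that starts heme synthesis, 1.86-fold (0.90 ± 0.12). Slc2a1, a glucose transporter, was 1.65-fold higher (0.72 ± 0.13), and Sfxn1, a mitochondrial serine transporter, 1.39-fold (0.48 ± 0.08).

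With limma, 16 genes were called under placebo, 6 higher and 10 lower in nulls, 12 of them at least 2-fold, and in all 16 the groups did not overlap. Adjusted p-values were 9.56e-05 for Gm6524, 0.00251 for Rgs3, Zc3h12d, Alas2 and Efr3b, 0.0139 for A330032P22Rik, 0.0176 for Sfxn1 and BC037704, 0.0359 for Slc2a1, 0.0361 for Rad51b, 0.0373 for Foxq1, and 0.0412 for Snhg11 and Slc26a4. The other kept Rgs3 probes differed by -0.21 and -0.69 (adjusted p of 0.908 and 0.119 over all probes), so the change held at 1 of 3 probes. The second probes of Snhg11 (1.21, adjusted p = 0.313) and Sfxn1 (0.41, 0.21) did not pass. Zc3h12d (7589850 to 7589909) and A330032P22Rik (6627168 to 6627227) lay on chromosome 10, as Esr1 does. The Rgs3 probe lay on chromosome 4 at 62363993 to 62364052, Gm6524 on chromosome 8 at 11693102 to 11693161 and Efr3b on chromosome 12 at 3962573 to 3962632. Alas2 lay on chromosome X at 147004993 to 147005052, Slc2a1 on chromosome 4 at 118809864 to 118809923 and Sfxn1 on chromosome 13 at 54203645 to 54203704. Esr1, Rgs3, Zc3h12d, Gm6524, Alas2 and Efr3b kept their calls without any single array, while Snhg11, Slc26a4, Foxq1, Rad51b and Slc2a1 lost theirs when any 1 of 15, 13, 11, 10 and 10 arrays was left out. BC037704 lost its call without null placebo 1, 2 or 4 or wild-type placebo 3, Sfxn1 without null placebo 2 or wild-type placebo 3, and A330032P22Rik without wild-type placebo 3. The call of Efr3b ended under normexp, quantile and median scaling, the deposited values and a fit of only the arrays compared, that of Alas2 under median scaling and only the arrays compared, and that of Rgs3 with the mean of its probes. Of the settings other than leaving out 1 array, 8 ended the call of Snhg11, 8 of Slc26a4, 9 of Sfxn1, 8 of BC037704, 7 of Foxq1, 6 of Slc2a1, 5 of Rad51b and 4 of A330032P22Rik. The count was 6 without wild-type placebo 3, 9 without null placebo 2, 10 without null placebo 4 or null E2 3 and 46 without null placebo 3. It was 46 with array weights, 30 with a trended robust fit, 9 with slide as a block, 8 without the filter or with only the arrays compared, 7 with median scaling and 2 without the animals numbered below 750, where Esr1 alone of the genes named here kept its call. The calls of Snhg11, Slc26a4, Slc2a1, Sfxn1, Foxq1, Rad51b and BC037704 ended with slide as a block. Of the placebo animals 3 nulls and 0 wild types were numbered below 750. With such animals as a block 22 genes were called, 10 of them among the 16. The calls of Slc26a4, Slc2a1 and A330032P22Rik were among those that ended. Within slides the named calls kept their sign in 42 of 42 values, which groups that do not overlap fix in advance.

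Camera called 12 lists for null against wild type under placebo, and 0 passed with an estimated correlation (smallest adjusted p = 0.138). All 25 cholesterol synthesis genes lay above 0 in nulls (median 0.46, camera adjusted p = 5.37e-10, adjusted p = 0.254 with an estimated correlation), with 3 adjusted over the list alone. Msmo1, a sterol oxidase gene, was 2.05-fold higher without passing (adjusted p = 0.32). Fatty acid synthesis (21 of 27, median 0.23, camera adjusted p = 0.00504, adjusted p = 0.536 with an estimated correlation, 0 over the list) shifted up. Glucose metabolism did so in 24 of 26 members (median 0.20, camera adjusted p = 5.36e-05, adjusted p = 0.248 with an estimated correlation, 0 over the list). Glucocorticoid targets had 18 of 20 members above 0 (median 0.44, camera adjusted p = 1.84e-06, adjusted p = 0.248 with an estimated correlation, 7 over the list), such as Sgk1, a kinase gene, 1.69-fold higher with an adjusted p of 0.193. Interferon response genes had 25 of 30 above 0 (median 0.27, camera adjusted p = 5.49e-06, adjusted p = 0.398 with an estimated correlation, 10 over the list), among them Irf7, 1.51-fold higher with an adjusted p of 0.199. Xenobiotic genes of the receptors CAR and PXR (23 of 27, median 0.18, camera adjusted p = 5.52e-05, adjusted p = 0.138 with an estimated correlation, 2 over the list) shifted up as well. So did pericentral genes (17 of 19, median 0.09, camera adjusted p = 0.00361, adjusted p = 0.138 with an estimated correlation, 2 over the list). Periportal genes lay above 0 in 16 of 19 members (median 0.21, camera adjusted p = 5.36e-05, adjusted p = 0.138 with an estimated correlation, 5 over the list). Male-biased genes were split, 12 above and 11 below 0 (median 0.05, mean 0.45, camera adjusted p = 0.0257, adjusted p = 0.697 with an estimated correlation, 5 over the list), and Cyp4a12a was 7.19-fold higher without passing (adjusted p = 0.164). The erythroid list lay above 0 in 8 of 8 members (median 0.39, camera adjusted p = 6.83e-08, adjusted p = 0.138 with an estimated correlation, 5 over the list), led by Alas2. Adipose markers did so in 5 of 5 (median 0.26, camera adjusted p = 0.0247, adjusted p = 0.138 with an estimated correlation, 0 over the list). Cell cycle genes lay below 0 in 19 of 24 (median -0.14, camera adjusted p = 0.0197, adjusted p = 0.536 with an estimated correlation, 0 over the list). These shifts and those of E2 in wild types use the same wild-type placebo arrays, whose erythroid mean of 3.27 ± 0.15 lay below 3.73 ± 0.21, 3.76 ± 0.27 and 3.65 ± 0.20 in wild types under E2 and nulls under placebo and E2 (SD, n = 5). Fry called 5 of the 12 lists, and 9 were called with only animals numbered 750 or above. Quantile scaling ended the calls of male-biased and cell cycle genes, and the deposited values that of cell cycle genes. Slide as a block ended the call of male-biased genes, and a block for the animals numbered below 750 those of adipose and cell cycle genes. The camera calls of fatty acid synthesis (wild-type placebo 4), adipose markers (null placebo 5, wild-type placebo 1), male-biased genes (null placebo 1 or 4, wild-type placebo 1 or 5) and cell cycle genes (null placebo 1 or 3, wild-type placebo 4 or 5) ended without the array named. Within slides 31 of 36 medians kept their sign.

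The last comparison set nulls against wild types after E2. Here 50 of the 70 genes called for E2 in wild types were called in the opposite direction in nulls. Slc34a2 was at least 21.7-fold lower (log2 -6.22 ± 0.39, SE, n = 5 per group, adjusted p = 3.63e-08) and Gdf15 15.6-fold (-3.97 ± 0.39, 1.51e-05). Krt4 was at least 2.55-fold lower (-2.97 ± 0.39, 0.000313). Corin (log2 -3.11 ± 0.40, 0.000254) and Trex2 (-2.94 ± 0.45, 0.00184) were lower with 1 of 5 null arrays each above background. Under normexp background correction the changes were -2.63 for Slc34a2, -1.16 for Corin, -0.60 for Krt4 and -0.88 for Trex2. Mthfd1l, an enzyme of mitochondrial one-carbon metabolism, was 2.75-fold higher in nulls (1.46 ± 0.20, adjusted p = 0.0004), and Catsper2 1.63-fold higher (0.70 ± 0.09, 0.000254). Gal3st1, a sulfotransferase gene of glycolipids (2.53-fold, adjusted p = 0.0478), Neu2, a sialidase gene (1.66-fold, 0.0414), and Cldn3, a tight junction gene (1.63-fold, 0.0467), were higher too. With limma, 102 genes were called, 17 higher and 85 lower in nulls, 50 of them at least 2-fold and 100 with groups that did not overlap. The second probes of Mthfd1l (0.83, adjusted p = 0.375 over all probes) and Catsper2 (0.44, 0.109) did not pass, and the call of Catsper2 ended with median scaling. The calls of Gal3st1, Cldn3 and Neu2 ended when any 1 of 17, 16 and 11 arrays was left out, and in 6, 8 and 6 other settings. The count was 67 without null E2 animal 2 or wild-type E2 animal 5, 39 with median scaling and 35 without the animals numbered below 750, which ended the calls of Krt4, Catsper2, Gal3st1, Neu2 and Cldn3. Those of Neu2 and Cldn3 ended with slide as a block too, and those of Gal3st1 and Cldn3 with slide as a random block. Within slides the named calls kept their sign in 36 of 36 values, which was fixed in advance for genes named for groups that do not overlap.

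Of the 70 genes called for E2 in wild types, 50 were called in the opposite direction in nulls against wild types under E2, where independent lists would share 0.258. Both comparisons use the wild-type E2 arrays. Simulated unchanged groups shared a median of 0 genes and at most 1 in 50 sets. With no changed gene in them, they cannot show how many of the shared genes come from the shared arrays. With the wild-type E2 arrays divided between the comparisons a median of 30.5 genes was shared (23 to 34 over 20 divisions). Null against wild type gave 5 genes under both placebo and E2, all in the same direction, where independent lists would share 0.043. These were Esr1, Zc3h12d, Rgs3, Gm6524 and a lincRNA region on chromosome 10, and Gm6524 fell by 1.12 under placebo and by 0.86 under E2. Of the 16 genes called under placebo 15 had the same sign under E2.

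**Figure D3:**
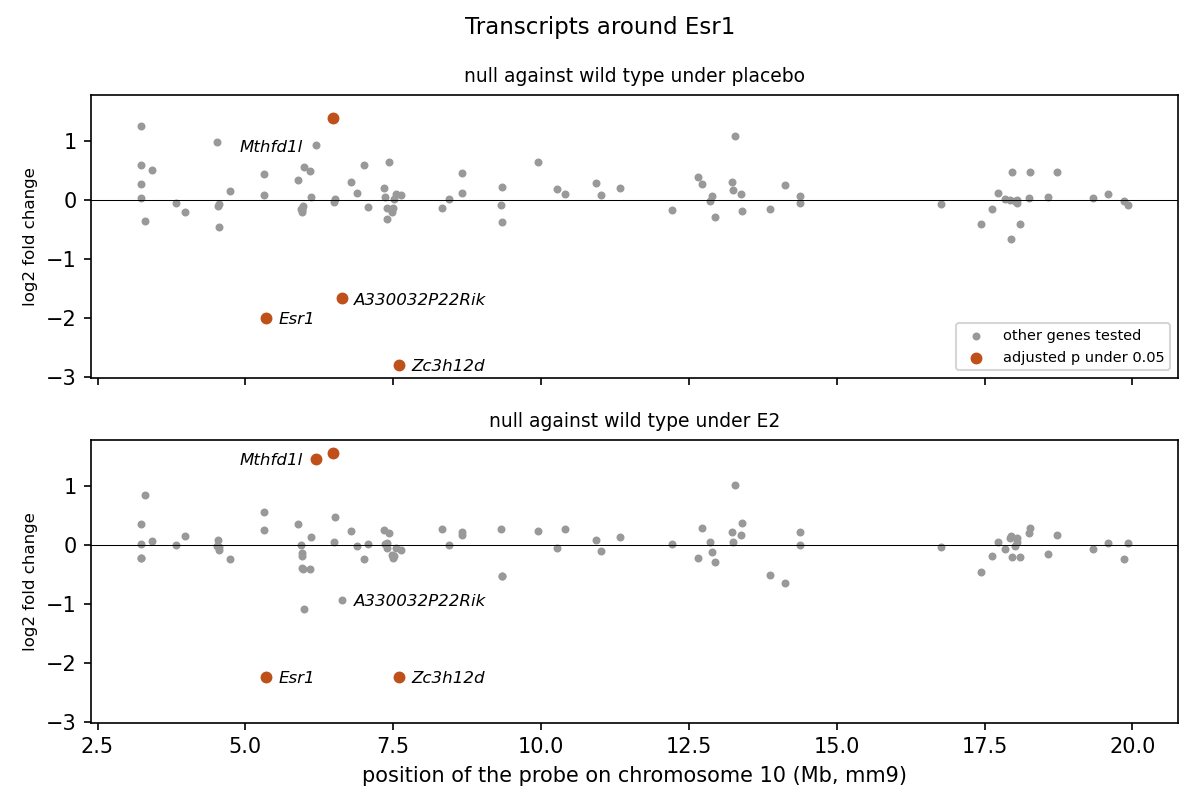
Log2 fold change of nulls against wild types under placebo (top) and E2 (bottom) for the genes tested on the first part of chromosome 10, by probe position on mm9, with called genes marked. Zc3h12d (7589850) lies at -2.79 and -2.23 and Esr1 (5343056) at -2.00 and -2.23.

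Camera called 5 lists under E2, and 0 passed with an estimated correlation (smallest adjusted p = 0.345). In nulls cholesterol synthesis lay above 0 in 22 of 25 members (median 0.21, camera adjusted p = 0.00176, adjusted p = 0.78 with an estimated correlation, 0 adjusted over the list alone). Xenobiotic genes did so in 22 of 27 (median 0.18, camera adjusted p = 0.000311, adjusted p = 0.345 with an estimated correlation, 5 over the list). Interferon response genes did so in 25 of 30 (median 0.25, camera adjusted p = 0.000233, adjusted p = 0.666 with an estimated correlation, 0 over the list). Immediate early genes lay below 0 in 18 of 25 (median -0.28, camera adjusted p = 0.0211, adjusted p = 0.666 with an estimated correlation, 1 over the list). Jund, which encodes an AP-1 subunit, was called at 1.82-fold lower (log2 -0.87 ± 0.18, adjusted p = 0.0349). Sinusoidal endothelial markers lay below 0 in 15 of 17 (median -0.19, camera adjusted p = 0.0318, adjusted p = 0.78 with an estimated correlation, 0 over the list). Cdh5, an endothelial cadherin gene, was 1.36-fold lower without passing (adjusted p = 0.518). The 29 estrogen targets had 19 members below 0 (median -0.16, camera adjusted p = 0.0699). The call of cholesterol synthesis ended without null E2 animals 2 or 5, that of immediate early genes without null E2 5 or wild-type E2 1 or 3. That of sinusoidal markers ended without null E2 1, 2, 3 or 5 or wild-type E2 2, 4 or 5, and that of Jund ended without null E2 2, 4 or 5 or wild-type E2 1, 2, 4 or 5. Camera called 3, 9, 2 and 8 lists without null E2 2, 4 and 5 and wild-type E2 4. With only animals numbered 750 or above 3 of the 5 were called, and the call of Jund ended, as it did with slide as a block. Within slides 13 of 15 medians kept their sign. In none of the 5 contrasts did camera call the lists of bile acid, lipoprotein, circadian clock, p53, growth hormone, steroid receptor or estrogen metabolism genes, or the cholangiocyte, B cell or neutrophil markers (smallest adjusted p = 0.0591, for bile acids).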

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

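Of the tests in this part, those of strain DNA and of the receptor's loss near Esr1, of the low-numbered cohort and growth hormone, and of blood in the piece of liver and slides for erythroid genes were chosen after the result was seen.

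E2 had effects that differed between genotypes by a test of the difference itself in 36 genes. The differences were 6.07 on the log2 scale for Slc34a2, 3.93 for Corin, 3.83 for Gdf15, 2.95 for Mmd2, 2.87 for Krt4 and -0.81 for Catsper2. For Slc34a2, Corin and Krt4, at or near background in the other groups, they were 2.60, 1.35 and 0.64 under normexp background correction.

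Divisions of the same arrays into groups of the same sizes were counted, 100 per comparison, and each count of 100 includes the real grouping itself. For genes, the real grouping gave 70 for E2 in wild types (highest other 2, as many in 1 of 100), 36 for the difference between genotypes (highest other 61, 2 of 100), 16 for nulls under placebo (highest other 76, 2 of 100) and 102 for nulls under E2 (highest other 3, 1 of 100). For E2 in wild types and nulls under E2 no other division gave as many, which argues against chance. For the difference and nulls under placebo the share was small, but another division gave more genes than the real one. Chance is thus argued against less firmly there. Chance cannot be excluded for the gene called for E2 in nulls, where 6 of 100 divisions gave as many and the highest other gave 2. For lists it cannot be excluded in any comparison, with as many in 44 (9 real, highest other 15), 10 (12, 15), 50 (8, 15), 19 (12, 16) and 62 (5, 11) of 100, in the order E2 in wild types, E2 in nulls, their difference, nulls under placebo and nulls under E2. The division that gave 76 genes, several times the real 16, points to a structure of the samples, whose source was not found. It set wild-type placebo 1, 2 and 3 with null placebo 1 and 3 apart from the rest, with slides mixed on both sides and 2 and 1 animals numbered below 750. The division that gave 61 genes for the difference grouped the placebo arrays in the same way, so this structure may bear on that count too.

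Genes near Esr1 differed between nulls and wild types. For the mean of both contrasts 153 genes were called. Of the 72 genes tested within 10 Mb of Esr1, 6 were called (8.33%), against 146 of 21753 elsewhere (0.671%, 1-sided Fisher's exact p = 1.11e-05, with genes as the units). They were Mthfd1l (1.19), a lincRNA region (1.48), A330032P22Rik (-1.29), Zc3h12d (-2.51), Sf3b5 (0.28) and Adat2 (1.05). This is what DNA of another mouse strain, carried along with the targeted locus, may give, and a variant under a probe stays open. Of the genes with several probes 1, the lincRNA region, differed the same way at all of them. Mthfd1l and Sf3b5 passed at 1 of 2 probes, and their second probes differed by 0.77 and 0.12 (adjusted p over all probes of 0.0924 and 0.424 by limma). Loss of the receptor acting on these genes cannot be told apart from strain DNA or such a variant, since 1 of them, Mthfd1l, moved with E2 in wild types against its change in nulls (-0.53, unadjusted p of 0.0141 by limma). Adat2 lay within the null range (0.67 to 1.48) in wild-type placebo 1 (0.88) and wild-type E2 4 (0.98), whose Esr1 levels were 0.59 and 0.83. Zc3h12d lay within the wild-type range in null E2 5 (-1.65). Single animals thus departed from their genotype at these genes, which does not settle the cause.

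Male-biased genes varied widely between animals of the same group (SD of the list mean 0.32 to 0.57). The spread was not theirs alone. The residual SD was 2.39 for Hsd3b5, of the male-biased list, and 2.91 for Sult2a1, of the female-biased list. Within groups, no difference between slides was found in the mean of the list (permutation p = 0.964). This gives no support to slides as the source. With 0 to 2 arrays of a group on a slide, the test could miss a slide effect. The 7 animals numbered below 750 had lower means than the other 8 animals of the same 3 groups (mean of the differences within groups -0.61, exact 2-sided permutation within groups p = 0.023), by -0.95, -0.06 and -0.81 in wild types under E2, nulls under placebo and nulls under E2, so a cohort stays open. Deviations of the list correlated with those of growth hormone and STAT5 genes over 20 arrays (r = 0.495, permutation p = 0.0267, rho = 0.589, p = 0.00679, 1 relation tested), and r was 0.506 (p = 0.0327) without the 2 arrays farthest from the median. That permutation moved deviations freely between groups, though those of a group cancel out, so its p-values tend to be too small. Growth hormone signalling that differed between animals at the time of death may thus contribute. The mean of those growth hormone genes was 2.47, 2.52 and 2.33 in low-numbered null placebo animals, against 3 and 2.71 in the others. In wild types under E2 it was 2.68 and 2.39 against 2.76, 2.76 and 2.77. In nulls under E2 it was 2.49 and 2.46 against 2.84, 2.81 and 2.34. The cohort and growth hormone thus cannot be told apart here, and both can hold together. Low-numbered null placebo 1 had the highest male-biased mean of all arrays (4.3).

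Erythroid genes lay above 0 in nulls against wild types under placebo in 8 of 8 members, with Alas2 the 1 called over all genes and a list adjusted p of 0.138 with an estimated correlation. The wild-type placebo mean (3.27) lay below the means of the other 3 groups, and adipose markers lay above 0 as well (5 of 5). Slides are argued against for Alas2, which kept 0.84 with slide as a block (adjusted p = 0.0129). For the mean of the 8 genes they are argued against as the whole source, since it was higher by 0.47 ± 0.13 (SE) with slide in a linear model and by 0.49 without. Within the 3 slides that held both groups it was higher by 0.48, which an exact 2-sided permutation within slides did not part from chance (p = 0.0556, with 36 arrangements whose smallest p is 0.0278). Both tests were run, and the linear model was made the deciding one, in place of the permutation, after both values had been seen. By the permutation alone slides would have stayed open for this mean. More blood in the piece of liver may account for the shift. The mean of the 5 globin genes was higher by 0.38 (exact 2-sided permutation p = 0.0397 over 252 splits), and the 2 other genes besides Alas2 rose beyond it by 0.19 (exact p = 0.23), which does not part blood from another source. Alas2 rose more than these, but it was noticed for its rise and so decides nothing. The genotype stays open as well, and so does any difference between these 10 animals that the labels do not give.

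Single arrays stood apart from the other 4 of their group in 15 of 244 groups of values (6.1%), where chance gives about 5%. The mean of negative controls was 43.78 on wild-type E2 1, against 26.28 to 31.14 on the others. Krt4 stood at -4.97 on wild-type placebo 1 and at -2.34 on wild-type E2 1, where the nearest others were -6.49 and -3.33. Slc26a4 stood at -2.93 on wild-type placebo 5, Alas2 at 3.92 on null placebo 1, Gm6524 at 1.16 on null E2 5, Mthfd1l at -0.27 on null placebo 4 and Gal3st1 at 0.05 on null placebo 2. On null E2 5 Zc3h12d also stood at -1.65, within the wild-type range of -1.86 to -0.63, while the other nulls were at -3.37 or lower. List means stood apart for endoplasmic reticulum stress on wild-type E2 5 (3.23), fatty acid oxidation on wild-type E2 1 (5.92), erythroid genes on wild-type placebo 5 (3.0), xenobiotic genes on null placebo 5 (4.95), glucocorticoid targets on null E2 2 (5.09), sinusoidal markers on null E2 4 (2.21) and fatty acid synthesis on null E2 5 (4.23).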

How the results depend on the processing

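Settings that use the animal numbers, and the list tests with arrays left out, were chosen after the result was seen. Counts are given in the order E2 in wild types, E2 in nulls, their difference, and nulls against wild types under placebo and under E2, against 70, 1, 36, 16 and 102 genes and 9, 12, 8, 12 and 5 lists as reported, and unless stated the cause was not tested. Gene counts with the authors' deposited values were 74, 1, 39, 14 and 109, and with quantile scaling 65, 1, 34, 11 and 93. The 10 largest increases with E2 in wild types passed in every setting that tested them, and Slc34a2, Corin, Krt4, Rab44 and Trex2 were not tested with the filter on all 20 arrays.

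Median scaling gave 32, 0, 18, 7 and 39 genes. Under it the median of all genes was -0.222, -0.117, -0.101, 0.01 and 0.114, against 0.002, -0.012, 0.017, 0.013 and -0.001 as reported. Only the arrays compared gave 46 genes for E2 in wild types, 0 in nulls and 8 for nulls under placebo, from fewer samples. For E2 in nulls no filter gave 0, the mean of probes 0 and slide as a fixed block 2. At each 0, limma had 829 to 1464 genes with an unadjusted p under 0.05. For nulls under placebo no filter gave 8, slide as a fixed block 9, array weights 46 and a trended robust fit 30. Only animals numbered 750 or above (5, 3, 2 and 3 per group, fewer samples) gave 41, 0, 10, 2 and 35 genes, and 5, 2 and 5 lists in the first 3 comparisons, of which 5, 0 and 2 were lists reported there. Leaving out 1 array gave 50 to 87, 0 to 2, 31 to 40, 6 to 46 and 67 to 119 genes, and 6 to 14, 6 to 16, 6 to 10, 10 to 17 and 2 to 9 lists. Lists passed in 0 cases with an estimated correlation in all 5 comparisons, and with fry in 2, 0, 0, 6 and 0 (2, 0, 0, 5 and 0 of those reported). For nulls under E2 normexp gave 10 lists and median scaling 9.

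The replicate numbers gave no clear pairing of the animals. Of 30 pairs with the same number 11 correlated above 0.1 (-0.163 to 0.245), and 3 of 20 arrays were closest to their own number. Pairs with the same number had a median correlation of 0.086, against -0.021 for the others (-0.314 to 0.304), so a weak likeness stays open. Within each group the replicate numbers rise with the animal numbers, so such a likeness cannot be told apart from the order of the animals. The replicate block gave 90, 0, 35, 13 and 92 genes.

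Some list medians changed direction. For E2 in nulls, acute phase was -0.175 to 0.025 when 1 array was left out (0.025 without null placebo 1) and 0.011 within slide 3, endoplasmic reticulum stress -0.248 to 0.017 when 1 array was left out (0.017 without null placebo 1) and 0.072 and 0.021 within slides 1 and 3, fatty acid oxidation -0.003 and -0.009 within slides 1 and 2, female-biased genes -0.04 and male-biased genes 0.13 within slide 2, Kupffer markers -0.23 within slide 1 and stellate markers 0.066 within slide 3. Coagulation had a median of -0.005 in animals numbered 750 or above, with camera's direction turned. For E2 in wild types, cell cycle was 0.172 within slide 4, endoplasmic reticulum stress 0.152 within slide 2, glucocorticoid targets -0.183 and -0.328 and immediate early genes -0.051 and -0.202 within slides 1 and 4, and Kupffer markers -0.004 within slide 1. For nulls under placebo, cell cycle was 0.004 within slide 3, fatty acid synthesis -0.213 and glucocorticoid targets -0.037 within slide 1, interferon genes -0.22 within slide 2, and male-biased genes -0.065 to 0.242 when 1 array was left out (-0.065 without null placebo 1) and -0.106 within slide 2. Further medians crossed 0, namely fatty acid oxidation for E2 in nulls (-0.026) and glucocorticoid targets (-0.009) and T and NK cell markers (-0.008) for E2 in wild types with median scaling, stellate markers for E2 in nulls in animals numbered 750 or above (0.027), and for nulls under placebo cell cycle with those below 750 as a block (0.002) and male-biased genes with quantile scaling (-0.009) and the deposited values (-0.005). Median scaling put the median of all genes at -0.222 for E2 in wild types and -0.117 for E2 in nulls. Its crossings of 0 are thus no turn of a list against the other genes. For nulls under E2, cholesterol synthesis was -0.344 within slide 1 and immediate early genes 0.038 within slide 4. Genes near background, such as Slc34a2 and Krt4 under placebo, have only a lower bound on their fold.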

Other observations

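The test of neighbouring genes and its windows, and the genes named here, were chosen after the result was seen.

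Other genes that E2 raised in wild-type livers spanned several functions. Stat5a, which encodes a transcription factor downstream of growth hormone and prolactin receptors, rose by 1.33 ± 0.15 on the log2 scale (SE, adjusted p = 4.7e-05), Il17ra, an interleukin receptor gene, by 1.91 ± 0.24 (adjusted p = 0.000157) and Mad2l1, a spindle checkpoint gene, by 2.10 ± 0.15 (adjusted p = 2.18e-07). Among lipid genes, Gpat3, an acyltransferase of glycerolipid synthesis, rose by 1.47 ± 0.16 (adjusted p = 2.69e-05), Insig2, a regulator of sterol synthesis, by 1.25 ± 0.26 (adjusted p = 0.0486) and Ehhadh, an enzyme of peroxisomal fatty acid oxidation, by 1.02 ± 0.21 (adjusted p = 0.0388). Aqp8, a water channel gene, rose by 1.19 ± 0.18 (adjusted p = 0.00145). The difference between genotypes passed for Mad2l1 (adjusted p = 5.86e-05), Gpat3 (0.00242), Il17ra (0.00611) and Aqp8 (0.0107) and not for Stat5a (0.0593), Insig2 (0.109) or Ehhadh (0.512).

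The array names 2 transcripts of a myosin XVB gene on chromosome 11 by accession alone. ENSMUST00000040703 (115748700 to 115748759) was well above background on 0 of 5 placebo arrays and 5 of 5 E2 arrays of wild types, a rise of at least 41-fold (fitted log2 difference 6.22, adjusted p = 2.18e-07), against a fitted 0.37 in nulls. ENSMUST00000093911 (115753436 to 115753495) rose 6.16-fold (adjusted p = 2.7e-09), against a log2 difference of -0.02 in nulls.

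Several genes that E2 raised in wild types lay next to each other. Of 60 such genes with symbols, 5 pairs had probes within 100 kb, namely Krt4 and Krt79 (9.6 kb, related keratin genes), Rab44 and Cpne5 (9.0 kb), Gdf15 and Pgpep1 (20.7 kb), Fanca and Zfp276 (1.2 kb) and Caskin2 and Tsen54 (23.7 kb). Random sets of 60 among 15914 tested genes gave a mean of 0.4 pairs and at most 6 (1-sided permutation p = 0.00022, 100000 resamples, with genes as the units). Windows of 50, 200, 500 and 1000 kb gave 5, 7, 7 and 10 pairs (permutation p = 2e-05, 0.00014, 0.00361 and 0.00344). An arbitrary placement of the genes is argued against by this test, though the closeness was found and tested on the same data. A candidate explanation, which was not tested, is a regulatory region that neighbouring genes share. Of the 5 pairs 3 lay on opposite strands and 2 on the same strand.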
